A study of Physcomitrium patens with 3 samples.

How the data were processed

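Double-stranded RNA sequencing was done on 10-day-old protonemata of wild type and of the rdr2 and rdr6 mutants, with 1 library each. Per the labels' protocols, total RNA was extracted with Tri-Reagent, depleted of ribosomal RNA with a Ribominus kit, treated with RNase One to remove single strands, and made into libraries with an Illumina small RNA kit for the GAIIx. The labels leave open how many rounds of depletion each library received. Per the submitters' processing notes, Bowtie 0.12.9 and SAMtools were used. The genome build, the locus caller, the mapping settings and the treatment of reads with several matching places are not given in the sources used here. Reads of repeated sequences may therefore be shared between loci, or placed at some of them only, and loci of a few bases may reflect how the list was built. Strand is not given, so both strands are counted together here.

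Each deposited table lists the same 39975 loci with coordinates, a cluster name, a raw count of reads and an RPM (reads-per-million) value, per the file headers. A prefix shared by all cluster names is left out here. Loci did not overlap. The count divided by the deposited RPM was the same at every locus of a library up to rounding, which gave library totals of 6992269 reads for wild type, 9703597 for rdr2 and 9346061 for rdr6. Counts in loci made up 84.8%, 89.6% and 86.4% of these totals, and the remainder was not analysed here. Multiplying RPM by the total and rounding to the nearest whole number gave back the count at 99.998%, 99.985% and 99.998% of loci, respectively. No count test was run on them, since 1 library per genotype leaves no residual degrees of freedom. Groups follow the genotype labels. The name of the deposited table of the rdr2 library carries another rdr number than its label, and the label was followed throughout.

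Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Ratios between libraries were ratios of RPM with exact Clopper-Pearson 95% intervals, taken from the share that one library has of the reads of both. The interval covers counting error only and no variation between libraries. PCR reads without molecular identifiers are not independent molecules, so it can be too narrow even for counting error. Loci with at least 20 reads summed over the 3 libraries were examined. A locus was called higher or lower when the ratio was at least 4 and the interval lay wholly beyond 2-fold. Where 1 of the libraries had no read, the ratio has no finite size and the call rested on the interval alone, so that the bound given can lie under 4. That bound was computed against a floor of 3 reads per library, about the one-sided 95% limit of a count of 0, which lies below the upper end of the two-sided interval. It leaves out counting error in the library that has reads, so the exact interval reaches smaller folds than the bound given. The log2 ratios used for medians and plots had a pseudocount of 0.5 reads, added before division by the library totals. It pulls low loci toward the inverse ratio of these unequal totals, not toward equal levels. A locus without a read in wild type and rdr2 thus has a log2 ratio of -0.47 for rdr2 to wild type. Medians have order-statistic 95% intervals. Compartment medians were set against 10000 random lists of the same size, each member drawn among the 100 other loci nearest in mean RPM. Neighbouring loci were consecutive loci no more than 10 kb apart, for which calls were shuffled 10000 times over nuclear loci. No p-values were computed.

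Except Cluster_16415, which was named after its values were seen, the loci named in the text were chosen by a rule fixed before the data were examined: the 10 highest and 10 lowest loci of each comparison, ordered by the interval bound nearest to 1, the 5 loci with most reads in each library, and the 4 members with most reads of each list. Of the gene lists fixed in advance (RNA-dependent RNA polymerases, other small RNA pathway genes, microRNA precursors, trans-acting siRNA loci, heterochromatic siRNA loci, transposons, structural RNAs, and several gene families), only the plastid and mitochondrial lists could be filled, because the loci carry no names. The gene table at hand is of assembly ASM5946719v1, whose chromosomes differ from the scaffolds of the loci, and it was not used. Regions of neighbouring loci, length classes and the loci circled in the plot of ratios were chosen after the values were seen.

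The code was tested on simulated data: Poisson counts with the real loci and library sizes, in which 200 loci were changed by 8-fold or 16-fold. The counts below cover only loci that reached the read minimum in the simulated libraries. Lowered loci that fell under it are left out, so the shares given for lowered loci overstate recovery among all of them. For rdr2 against wild type, 0 of 3606 unchanged loci were called. Of the examined loci, 28 of 41 made 8-fold lower and 50 of 50 made 8-fold higher were called. For rdr6 against wild type, 1 of 3586 unchanged loci was called. Of the examined loci, 33 of 45 made 8-fold lower and 49 of 50 made 8-fold higher were called. For rdr6 against rdr2, 0 of 3585 unchanged loci were called, with 30 of 36 and 50 of 50 examined loci recovered in the same order. These simulations hold no variation between libraries beyond counting.

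Alternatives chosen in advance were TMM factors from edgeR 4.0.16, median-of-ratios size factors from DESeq2 1.42.0 (R 4.3.3), RPM of the reads outside the 1% of loci with most reads, read minimums of 10, 50 and 1, a ratio of at least 2 with an interval beyond 1, a ratio of at least 8, a pseudocount of 2 reads and pooled reads in place of medians. Removal of loci of 30 bp or less and other gaps between neighbours were added later.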

Results

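The series profiled double-stranded RNA in protonemata, the filamentous juvenile tissue of the moss Physcomitrium patens, at 10 days of age. Total RNA from wild type and from the rdr2 and rdr6 mutants was depleted of ribosomal RNA, digested with a nuclease specific for single strands, and sequenced. RDR2 and RDR6 are RNA-dependent RNA polymerases, enzymes that copy single-stranded RNA into double strands. In known plant pathways RDR2 acts in the production of heterochromatic small interfering RNAs and RDR6 in that of trans-acting small interfering RNAs. The design therefore asks which loci give fewer or more double-stranded RNA reads when either enzyme is missing. There was 1 library per genotype, so no difference below has a replicate check, no test between genotypes was possible, and higher and lower describe these 3 libraries. The deposited table of the library labelled rdr2 carries another rdr number in its name, and the label was followed. Intervals of ratios and shares are exact 95% intervals and cover counting error only. Those of medians are order-statistic 95% intervals over loci. They treat loci as independent and cover no variation between libraries.

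Reads were listed at the same 39975 loci in each library. Of these, 39907 lay on 1024 nuclear scaffolds, 17 on the plastid genome and 51 on the mitochondrial genome. The loci had a median length of 20 bp, and 72.9% were 30 bp or shorter. They carry cluster numbers and coordinates on a build that is not given in the sources used here, and no gene names. The RDR2 and RDR6 genes were therefore not checked in the libraries, and it is not stated here whether a locus is exonic, intronic or intergenic. The wild-type library held 5926254 reads in loci, the rdr2 library 8698124 and the rdr6 library 8078929. A single read was worth 0.143 RPM, the deposited reads-per-million value, in wild type, 0.103 in rdr2 and 0.107 in rdr6. The floor of 3 reads, about the one-sided 95% limit of a count of 0, was 0.429, 0.309 and 0.321 RPM, respectively. At least 1 read was found at 11570 loci in wild type, 8636 in rdr2 and 13053 in rdr6, and 23791 loci had no read in any library. Ratios were examined at the 3763 loci with at least 20 reads over the 3 libraries.

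A small number of loci held nearly all reads. The 400 loci with most reads, 1% of the list, took 97.46% of locus reads in wild type (95% Clopper-Pearson interval 97.44 to 97.47), 99.1% in rdr2 (99.1 to 99.1) and 97.3% in rdr6 (97.3 to 97.4). Nuclear loci took 70.7% of locus reads in wild type, 84.8% in rdr2 and 66.4% in rdr6. Plastid loci took 27.9%, 14.7% and 32.3%, and mitochondrial loci 1.38%, 0.522% and 1.33%, in the same order. The locus with most reads in every library was Cluster_39920 on the plastid genome (86071 to 94734), with 826377 reads in wild type, 829204 in rdr2 and 1413382 in rdr6. The 5 nuclear loci with most reads in rdr2 held 39.3% of the locus reads of that library (39.3 to 39.3). They held 15.5% of those of wild type (15.4 to 15.5) and 11.9% of those of rdr6 (11.91 to 11.96). Among them Cluster_39122, Cluster_39121, Cluster_39800 and Cluster_39201 had similar counts, with 710340, 701288, 686487 and 681399 reads in rdr2. In wild type they had 204809, 200556, 174191 and 170920. Whether these loci share reads of a repeated sequence was not tested, so they may not be separate. Nuclear loci outside the top 1% held 2.51% of locus reads in wild type, 0.925% in rdr2 and 2.63% in rdr6.

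**Figure D1:**
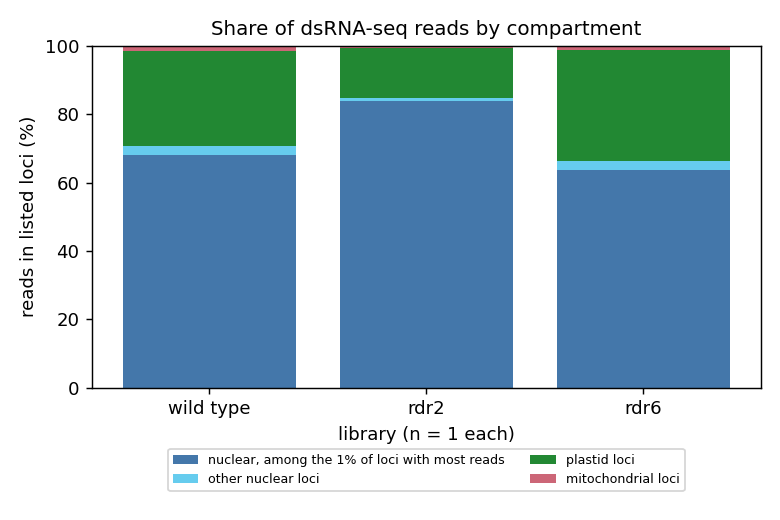
Share of reads in listed loci (%, vertical axis) by compartment in the wild-type, rdr2 and rdr6 libraries (n = 1 each). Plastid loci held 27.9%, 14.7% and 32.3% of reads, and nuclear loci outside the 1% of loci with most reads held 2.51%, 0.925% and 2.63%.

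The first comparison set rdr2 against wild type. On the authors' RPM scale, double-stranded RNA reads were lower in rdr2 at most loci, and the plastid median stood furthest below wild type. Pooled over loci the order turned, with plastid reads 1.80-fold and mitochondrial reads 2.49-fold lower. A few abundant nuclear loci were higher. The size rule, a ratio of at least 4 with an interval wholly beyond 2-fold, was met by 987 loci lower in rdr2 and by 19 higher. All 17 plastid loci lay below wild type on this scale, and 15 under each of 3 other scalings, where Cluster_39920 and Cluster_39923 lay above it. Of the 17, 14 met the size rule, and the median was 17.5-fold lower (log2 -4.13, interval of the median -4.54 to -2.53). That median lay below all 10000 random lists of the same size and mean level, whose central 95% ran from -2.42 to -0.59. Plastid loci share a genome and are not replicates, whereas each list member was drawn separately. The place among the lists therefore describes these libraries and is no test. All 37 mitochondrial loci lay below wild type on the RPM scale, 22 of them past the size rule, and 35, 33 and 31 lay below it with TMM factors, median-of-ratios size factors and the reads outside the top 1%, where 2, 1 and 1 met the size rule as lower. Their median of -2.08 stood at percentile 11.5 of the random lists. Nuclear loci had a median log2 ratio of -1.41 (-1.45 to -1.37), with 951 of 3709 loci lower and 19 higher.

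The loci lowest in rdr2 lay on the plastid genome and on separate scaffolds. Cluster_39916 on the plastid genome (73757 to 77829) had 22589 reads in wild type, 450 in rdr2 and 29605 in rdr6, which was 69.7-fold lower in rdr2 (63.5 to 76.6). Cluster_8975 (scaffold_34, 2138772 to 2138893) had 1146 reads in wild type and 16 in rdr2, 99.4-fold lower (60.9 to 174). Cluster_39749 (scaffold_2377, 29 to 251) had 2166 reads in wild type and 41 in rdr2, 73.3-fold lower (53.9 to 102). Cluster_23090 (scaffold_138, 334980 to 335122) was 81.9-fold lower (44.2 to 172), and Cluster_37312 (scaffold_410, 29097 to 29251) was 69.0-fold lower (33.1 to 173). Cluster_27985 (scaffold_201, 626564 to 626574) had 298 and 4 reads, 103-fold lower (40.0 to 382). Cluster_17996 (scaffold_91, 275187 to 275516) had 155 reads in wild type and 2 in rdr2, a ratio of 108-fold with an interval from 29.3 to 896. No rdr2 read was found at Cluster_35061 (scaffold_336, 25480 to 25494), Cluster_13394 (scaffold_59, 1579789 to 1579803) or Cluster_29844 (scaffold_231, 285910 to 285924). Against a floor of 3 reads in the rdr2 library these were at least 72.6-fold, 48.1-fold and 38.4-fold lower. All folds of this paragraph are on the RPM scale and were smaller under the 3 other scalings. The log2 ratio of Cluster_8975 was -6.59 in RPM and -5.62 with TMM factors. It was -5.37 with median-of-ratios size factors and -5.22 with the reads outside the top 1%.

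The loci higher in rdr2 included short nuclear loci and the most abundant nuclear loci of that library. Cluster_15637 (scaffold_74, 276091 to 276105) had 21 reads in wild type, 1851 in rdr2 and 61 in rdr6, which was 63.5-fold higher in rdr2 than in wild type (41.4 to 103). Folds here are on the RPM scale, and those above wild type were larger under the 3 other scalings. For Cluster_15637 the log2 ratio was 5.96 in RPM and 6.92 with TMM factors. It was 7.18 with median-of-ratios size factors and 7.32 with the reads outside the top 1%. Cluster_3109 (scaffold_9, 2689379 to 2689674) was 19.1-fold higher (11.8 to 33.0), Cluster_26830 (scaffold_185, 722019 to 722299) 10.8-fold higher (7.76 to 15.5), and Cluster_13890 (scaffold_62, 1807386 to 1807533) 8.71-fold higher (5.78 to 13.7). Cluster_32745 (scaffold_281, 116037 to 116044), Cluster_8391 (scaffold_32, 933247 to 933469) and Cluster_20854 (scaffold_115, 653118 to 653251) were 6.88-fold, 6.82-fold and 6.40-fold higher. Cluster_3329 (scaffold_10, 2285211 to 2285227) had 172 reads in wild type and 1122 in rdr2, 4.70-fold higher (4.0 to 5.55). Cluster_5405 (scaffold_18, 1687978 to 1688083) and Cluster_8043 (scaffold_30, 1468921 to 1468926) had no wild-type read and 33 and 25 reads in rdr2, at least 7.93-fold and 6.01-fold higher against a floor of 3 reads in the wild-type library. Of the 19 higher loci, 12 were 30 bp or shorter, against 34 of 74, 44 of 106 and 51 of 130 with TMM factors, median-of-ratios size factors and the reads outside the top 1%. Among all 3763 examined loci, 693 were that short. The abundant nuclear loci did not reach a ratio of 4 on the RPM scale, but the 4 named next exceeded it under each of 3 other scalings. Cluster_39122 (scaffold_699, 6871 to 10023) was at 2.499-fold of its wild-type level (2.49 to 2.51), Cluster_39121 (scaffold_699, 4995 to 6256) at 2.52-fold, Cluster_39800 (scaffold_4104, 7802 to 9028) at 2.84-fold and Cluster_39201 (scaffold_758, 1 to 959) at 2.87-fold. Cluster_39120, which lies next to them (scaffold_699, 1158 to 4519), was 2.22-fold below wild type on the same scale (2.21 to 2.24), but above it with median-of-ratios size factors and with the reads outside the top 1%.

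The 2 plastid loci with most reads differed less from wild type than the other plastid loci on the RPM scale and with TMM factors, whereas Cluster_39913 lay nearer to wild type with the other scalings. Plastid Cluster_39920 and Cluster_39923 (107750 to 122031) were 1.38-fold and 1.47-fold below wild type in rdr2 on the RPM scale, and above it under each other scaling. Cluster_39913 (24196 to 45144) was 2.97-fold and Cluster_39914 (45351 to 67525) 4.42-fold below it, and the 15 plastid loci other than the 2 largest were together 5.15-fold lower (5.12 to 5.18). Mitochondrial Cluster_39942 (33493 to 37523), Cluster_39941 (25756 to 33211), Cluster_39930 (7743 to 15394) and Cluster_39962 (80461 to 86286) were 2.43-fold, 1.82-fold, 3.74-fold and 6.60-fold below wild type, with Cluster_39941 above it under each other scaling and Cluster_39942 above it with the reads outside the top 1%. With the libraries rescaled to the reads outside the top 1% of loci, the median over all 3763 loci moved from -1.41 to -0.04, and the split changed from 987 lower and 19 higher to 217 lower and 130 higher. The plastid median was then -2.76. TMM factors gave 348 lower and 74 higher, and median-of-ratios size factors 261 and 106.

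The second comparison set rdr6 against wild type. Here the libraries differed at few loci: 57 were lower in rdr6 and 58 higher by the size rule, and all of them were nuclear. Neighbouring loci tended to differ together, and 2 regions were over 10-fold lower in rdr6 while they were 2.36-fold and over 2-fold above wild type in rdr2. The plastid median was -0.03 (-0.10 to 0.21) and the mitochondrial median -0.20 (-0.30 to -0.09), with no organelle locus past the size rule. They stood at percentiles 6.66 and 0.05 of random lists of the same size and mean level. Loci of the same organelle genome are not replicates, so these percentiles describe the libraries and are no test. The nuclear median was 0.11 (0.08 to 0.14) on the RPM scale, but -0.0057 with TMM factors.

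The region on scaffold_82 from 31723 to 38664 holds Cluster_16760 (31723 to 32373) and Cluster_16761 (38134 to 38664). Together they had 229 reads in wild type, 749 in rdr2 and 21 in rdr6, or 32.8, 77.2 and 2.25 RPM. This was 14.6-fold lower in rdr6 than in wild type (9.31 to 24.003). Cluster_16760 alone was 19.9-fold lower (9.77 to 47.1). The region on scaffold_210 from 800103 to 803986 holds 5 loci, of which Cluster_28553, Cluster_28556 and Cluster_28557 met the size rule. It had 112 reads in wild type, 338 in rdr2 and 12 in rdr6, 12.5-fold lower in rdr6 than in wild type (6.87 to 24.9). Cluster_28557 (803526 to 803986) was 26.7-fold lower (6.93 to 228), with 40 reads against 2. Regions on scaffold_66 (839941 to 841234) and scaffold_114 (1060518 to 1061095) were 8.69-fold (4.92 to 16.5) and 11.8-fold lower (5.08 to 33.6) in rdr6. In rdr2 the latter regions were 3.32-fold and 3.07-fold below wild type on the RPM scale, where the nuclear median was 2.65-fold below it.

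Other loci lowest in rdr6 had few or no reads in either mutant. Cluster_13394 (scaffold_59) had 104 reads in wild type, 0 in rdr2 and 1 in rdr6, a ratio of 139-fold in rdr6 with an interval from 24.4 to 5543. Cluster_35223 (scaffold_341, 140916 to 140931) had 91, 2 and 3 reads and was 40.5-fold lower in rdr6 (13.4 to 200.2). Cluster_29844 (scaffold_231) had 83, 0 and 3 reads, 37.0-fold lower in rdr6 (12.2 to 183), and Cluster_17996 (scaffold_91) had 155, 2 and 12 reads, 17.3-fold lower (9.61 to 34.1). Cluster_14768 (scaffold_68, 1200286 to 1200308), Cluster_5382 (scaffold_18, 1587907 to 1589196) and Cluster_25171 (scaffold_163, 343114 to 343144) had 36, 28 and 27 reads in wild type and 0 in both mutants. They were at least 16.0-fold, 12.5-fold and 12.03-fold lower in rdr6 against a floor of 3 reads in that library. Cluster_9551 (scaffold_37, 2031080 to 2031359) had 38 reads in wild type, 6 in rdr2 and 0 in rdr6, at least 16.9-fold lower in rdr6.

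Among the loci higher in rdr6, 27 of 58 fell in 10 regions in which called loci lay within 10 kb of each other. The region on scaffold_213 from 572373 to 574485 had 34 reads in wild type, 22 in rdr2 and 878 in rdr6, 19.3-fold higher in rdr6 than in wild type (13.7 to 28.1). Within it Cluster_28748, Cluster_28751 and Cluster_28752 were 44.9-fold (12.2 to 375), 16.3-fold (10.7 to 25.9) and 20.5-fold higher (10.6 to 45.4). The region on scaffold_55 from 1810616 to 1812602, which includes Cluster_12827, was 12.7-fold higher (8.41 to 20.03), that on scaffold_42 from 1603284 to 1607939, which includes Cluster_10511, 14.3-fold higher (8.39 to 26.6), and that on scaffold_89 from 771377 to 772851, which includes Cluster_17816, 13.3-fold higher (7.48 to 26.2). The regions on scaffold_44 (769842 to 778537) and scaffold_257 (437019 to 438963) each held 4 called loci and were 7.51-fold (5.78 to 9.91) and 6.08-fold higher (4.47 to 8.45). Single loci with large ratios were Cluster_22924 (scaffold_136, 466699 to 467218) with 2, 2 and 128 reads in wild type, rdr2 and rdr6, Cluster_2815 (scaffold_8, 2028588 to 2028601) with 2, 0 and 132 reads, and Cluster_27151 (scaffold_190, 318965 to 319114) with 1, 1 and 54 reads. Their ratios were 47.9-fold (12.99 to 399.6), 49.4-fold (13.4 to 412) and 40.4-fold (6.95 to 1625). Cluster_22907 (scaffold_136, 325721 to 325735) had 94 reads in rdr6 and none in the other libraries, at least 23.4-fold higher than in wild type.

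Calls of the same direction at consecutive loci no more than 10 kb apart numbered 17 pairs among the loci higher in rdr6 and 5 among those lower. With the calls shuffled 10000 times over nuclear loci, the mean was 0.307 pairs for the higher loci and 0.305 for the lower, and no shuffle gave more than 4 pairs of either kind. Rescaling the libraries left between 50 and 58 loci higher and between 57 and 64 lower. The 25 named loci that met the size rule in this comparison met it under each of the 3 other scalings.

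**Figure D2:**
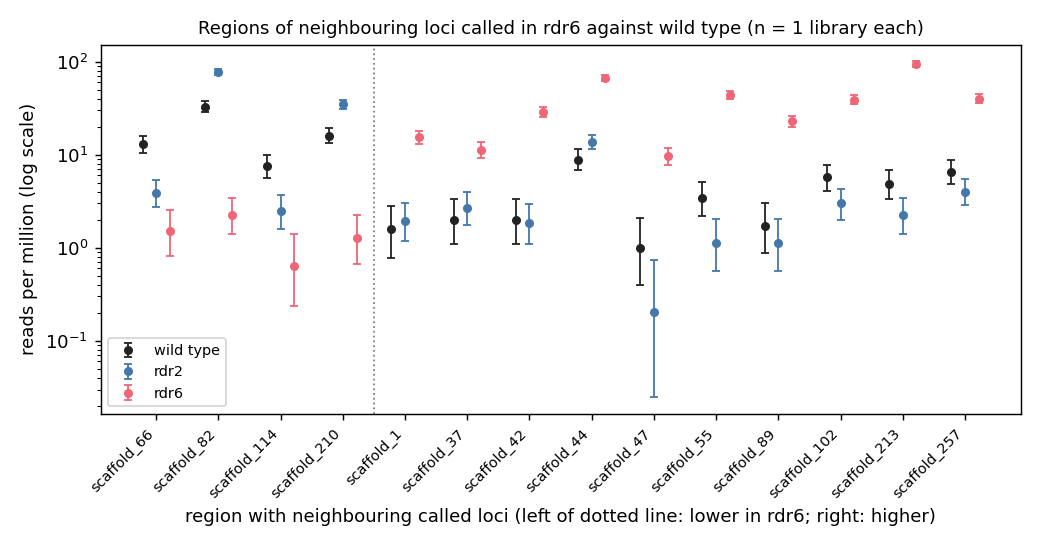
Reads in RPM (log scale, vertical axis) in the 14 regions where neighbouring loci met the size rule in rdr6 against wild type, with exact 95% counting intervals (n = 1 library each). In the scaffold_82 region the values were 32.8 in wild type, 77.2 in rdr2 and 2.25 in rdr6, and in the scaffold_213 region 4.86, 2.27 and 93.9.

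The third comparison set the mutants against each other, which leaves out the wild-type library. Reads were higher in rdr6 than in rdr2 at 1188 loci and lower at 38 on the RPM scale, and rescaling to the reads outside the top 1% gave 301 and 215. TMM factors gave 470 and 149, and median-of-ratios size factors 380 and 177. The loci lowest in rdr6 relative to rdr2 included the scaffold_82 and scaffold_210 regions. The scaffold_82 region was 34.4-fold lower in rdr6 than in rdr2 (22.3 to 55.8) and the scaffold_210 region 27.1-fold lower (15.3 to 53.0). Within them Cluster_16760, Cluster_16761 and Cluster_28557 were 41.9-fold, 29.7-fold and 49.6-fold lower, and Cluster_28556 (802642 to 802977) and Cluster_28553 (800103 to 800521) 36.0-fold and 16.9-fold lower. Another region, on scaffold_309 (404989 to 406360), which includes Cluster_34107, was 7.76-fold lower (4.67 to 13.7). Cluster_15637, Cluster_3109, Cluster_26830 and Cluster_13890, all above wild type in rdr2, were 29.2-fold, 18.1-fold, 6.78-fold and 7.46-fold lower in rdr6 than in rdr2. At the other end, Cluster_39749, plastid Cluster_39916, Cluster_23090, Cluster_8975 and Cluster_37312 were 93.2-fold, 68.3-fold, 99.9-fold, 78.8-fold and 67.6-fold higher in rdr6 than in rdr2. Cluster_30647 (scaffold_246, 118019 to 118046) and Cluster_19258 (scaffold_100, 1351848 to 1351937) were 47.5-fold (31.8 to 74.5) and 45.3-fold higher (29.5 to 73.6). Cluster_2815, Cluster_28748 and Cluster_21682 (scaffold_123, 1226300 to 1226715) had no rdr2 read and were at least 45.7-fold, 41.5-fold and 39.1-fold higher in rdr6. These folds are on the RPM scale. Under each other scaling, those higher in rdr6 were smaller and those lower in rdr6 larger. The log2 ratio of Cluster_39749 was 6.53 in RPM and 5.44 with TMM factors. It was 5.28 with median-of-ratios size factors and 5.07 with the reads outside the top 1%.

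Loci lower in both mutants than in wild type numbered 33, and 1 locus was higher in both. The latter, named after its values were seen, was Cluster_16415 (scaffold_79, 853676 to 853690) with 0 reads in wild type, 14 in rdr2 and 12 in rdr6, at least 3.36-fold and 2.99-fold higher against a floor of 3 reads in the wild-type library, and called on the interval alone, since a ratio to 0 has no finite size. Independent lists of these sizes would share 14.95 lower loci and 0.293 higher ones. In 100 sets of simulated unchanged libraries against a shared wild type, no lower locus was shared and at most 2 higher loci were, but such libraries hold almost no called loci, so these values say little of the overlap. On the scale of reads outside the top 1% the shared lower loci numbered 20, against 3.69 for independent lists. Loci higher in both numbered 0 with TMM factors, 2 with median-of-ratios size factors and 1 with the reads outside the top 1%. The log2 ratios of both mutants had a covariance of 0.239 across the 3763 loci, against 0.151 in the simulated unchanged libraries, and a correlation of 0.17 against 0.59. Loci are not independent replicates, the single wild-type library could not be split, and part of the overlap may come from it.

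**Figure D3:**
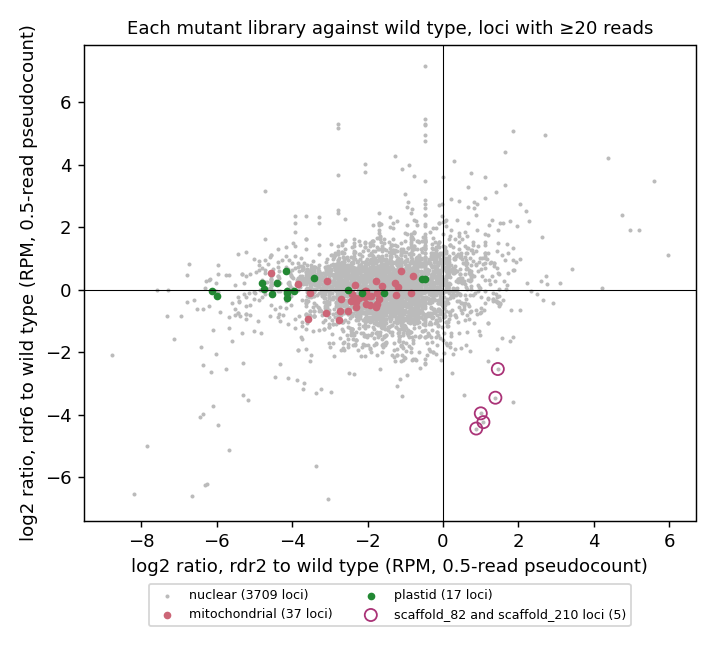
log2 ratio of rdr6 to wild type (vertical axis) against that of rdr2 to wild type (horizontal axis), in RPM with a pseudocount of 0.5 reads, at the 3763 loci with at least 20 reads (n = 1 library per genotype). Plastid loci have a median of -4.13 on the horizontal axis and -0.03 on the vertical axis, and 5 circled loci on scaffold_82 and scaffold_210, marked after their values were seen, lie above 0 in rdr2 and below 0 in rdr6.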

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

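The correlation between neighbouring loci was chosen as a test before its result was seen. The other tests were chosen after, although the compartment medians and the counts and medians after rescaling that some of them use had been set in advance. Loci past the size rule in opposite directions in both mutants were singled out; the difference between mutants was not tested, since there is 1 library of each. On the RPM scale this was Cluster_21682, with 9 reads in wild type, 0 in rdr2 and 113 in rdr6, and a log2 ratio of rdr6 to rdr2 of 7.88; it did not meet the size rule in rdr2 under the 3 other scalings. In the other direction, higher in rdr2 and lower in rdr6, there were 0 loci on the RPM scale, 3 with TMM factors (Cluster_16760, Cluster_16761 and Cluster_28553), and 5 with median-of-ratios size factors or the reads outside the top 1%. Values with median-of-ratios size factors follow. On scaffold_82 Cluster_16760 and Cluster_16761 had log2 ratios of rdr6 to rdr2 of -6.55 and -6.09. On scaffold_210 Cluster_28553, Cluster_28556 and Cluster_28557 had -5.23, -6.20 and -6.56.

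The first pattern is the lower level of most loci in the rdr2 library. The rdr2 library was not smaller, with 8698124 reads in loci against 5926254 in wild type, although fewer of them lie outside the top 1%. Since RPM already divides by the library total, this comparison says little on its own. A few loci taking most of the reads would lower all others by one factor. That factor alone would leave no gap between compartments, but the plastid median lay -2.72 on the log2 scale from the nuclear median. Pooled reads went the other way, at -0.85 for plastid loci and -1.36 for nuclear loci outside the top 1%. A further difference between 2 single libraries could also give the gap, so it does not decide whether such a factor acted. For nuclear loci the question stays open as well. Rescaling to the reads outside the top 1% nearly centres their median, at -0.04 over all loci. The 347 loci that then met the size rule decide nothing, because 2 single libraries are set against counting error alone. A different number of ribosomal RNA depletion rounds could raise abundant nuclear loci. Of these, the 5 with most reads in rdr2 were 2.69-fold higher, by a choice that favours high values there. Those loci may share reads and then not be 5 separate loci. All 368 in the top 1% together were 1.30-fold higher, but they include the same 5 loci. The 5 held 352417 of the 751771 RPM of the 368 in rdr2, and 130989 of 577721 in wild type. The others together were thus not higher in rdr2 on the RPM scale. Such a difference in rounds cannot be told apart from loss of RDR2, since the labels do not give the rounds per library.

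The second pattern is the lower level of the scaffold_82 and scaffold_210 regions in rdr6. The scaling of the libraries would move every locus by one factor, which the median log2 ratio of 0.10 over all loci argues against. The smaller of the lower bounds of the fold, 6.87, decides nothing on counting error, because the regions were picked by loci whose intervals lay beyond 2-fold. A candidate explanation is that double-stranded RNA from these regions depends on RDR6. Variation between libraries of one genotype cannot be told apart from it with 1 library per genotype, and reads shared with other copies of the sequence were not tested.

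The third pattern is that loci higher in rdr6 lie next to each other. Scatter of the calls over loci is argued against by the 17 neighbouring pairs, when no shuffle gave more than 4. A single RNA or region listed as several loci may explain it. Across loci, the log2 ratio of rdr6 to wild type correlated at 0.51 between 1286 pairs of loci within 10 kb. Between 2422 other consecutive pairs it correlated at 0.04. These values include the called pairs and extend the same pattern to all examined nuclear loci. Separate loci that change together would give them too, so the correlation cannot tell these explanations apart. If a single RNA or region was listed as several loci, the regions rather than the loci are the units that differ. Whether they differ by genotype or by library stays open.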

How the results depend on the processing

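The cause of each change below was not tested unless stated. In rdr2 against wild type, 74, 106 and 130 loci were higher and 348, 261 and 217 lower with TMM factors, median-of-ratios size factors and reads outside the top 1%. In rdr6 against rdr2 the same scalings gave 470, 380 and 301 higher and 149, 177 and 215 lower. Counts of rdr6 against wild type stayed within 1.5 times under them, and loci lower in both mutants numbered 21 and 20 with the latter 2. A minimum of 50 reads, which tests fewer loci, gave 35 higher and 30 lower in rdr6 against wild type and 11 lower in both mutants. The looser rule (ratio of 2, interval beyond 1) gave, higher and lower, 79 and 2089 for rdr2 against wild type, 302 and 285 for rdr6 against wild type, 2179 and 140 for rdr6 against rdr2, and 195 lower in both; the stricter rule (ratio of 8) gave 10 and 494, 33 and 27, 703 and 18, and 20. Without loci of 30 bp or less, an alternative chosen after seeing the data, 7 loci were higher in rdr2, 24 were lower in rdr6 than in rdr2, and 19 were lower in both mutants. Median log2 ratios for rdr2 with the 3 scalings in that order were -0.44, -0.19 and -0.0364 in nuclear and -1.11, -0.86 and -0.71 in mitochondrial loci. The nuclear rdr2 median was -1.36, -1.53 and -1.10 with minimums of 10, 50 and 1 read and -1.30 with a pseudocount of 2. The nuclear rdr6 median turned to -0.0057 with TMM factors and was 0.0194 with reads outside the top 1% and 0.0668 with a minimum of 1 read. For rdr6 the plastid median was -0.14 with TMM factors and -0.12 with reads outside the top 1%, and the mitochondrial median -0.31 with TMM factors. Pooled reads, which weight the most abundant loci, turned the nuclear values to 0.35 for rdr2 and -0.0624 for rdr6, and gave -0.85 and 0.24 for plastid and -1.32 and -0.016 for mitochondrial loci. The rdr2 median of nuclear loci over 200 and up to 1000 bp turned to 0.108 with reads outside the top 1%, and that of loci over 1000 bp to 0.1255 with median-of-ratios size factors and 0.2744 with reads outside the top 1%, alternatives chosen after seeing the data. Neighbouring pairs in rdr6 stayed within 1.5 times under every alternative run. Of 30 named loci called in rdr2 against wild type, 26 were called under each other scaling, and Cluster_9551, Cluster_21682, Cluster_39914 and Cluster_39962 were not. In rdr6 against rdr2 this held for 35 of 37, without the latter 2, and in rdr6 against wild type for 25 of 25. No named called locus changed direction under these scalings. Shares of reads per compartment have no alternative. Depth outside the top 1% of loci was 150816 reads in wild type, 81015 in rdr2 and 214593 in rdr6, which limits what can be seen in rdr2. No paired analysis was possible because each genotype has 1 library.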

Other observations

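The length classes and the counts of neighbouring pairs in this part were chosen after the data were seen. Nuclear loci of up to 200 bp had lower median ratios of rdr2 to wild type than longer ones, and the intervals of the classes up to 200 bp overlapped. On the RPM scale, loci of 30 bp or less had a median log2 ratio of -1.70 (-1.81 to -1.56), with 216 of 693 lower by the size rule, or 31.2%. Loci of 31 to 200 bp had a median of -1.78 (-1.88 to -1.67), with 390 of 1052 lower, or 37.1%. Loci over 200 and up to 1000 bp had a median of -1.26 (-1.31 to -1.21), with 307 of 1681 lower, or 18.3%. Loci over 1000 bp had a median of -1.09 (-1.19 to -0.95), with 38 of 283 lower. With the reads outside the top 1% as the scale, the medians were -0.33, -0.41, 0.11 and 0.27 in the same order, the classes over 200 bp thus above wild type. On that scale 57, 99, 40 and 8 loci were lower and 51, 27, 41 and 11 higher. In rdr6 the medians were 0.27, 0.25, 0.02 and -0.18 on the RPM scale, of which 0.02 was below 0 under each of 3 other scalings.

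Consecutive loci within 10 kb of each other were both lower in rdr2 than in wild type in 119 nuclear pairs on the RPM scale. The mean was 84.5 nuclear pairs in 10000 shuffles of the calls, 1 of which gave as many or more. With median-of-ratios size factors there were 9 such pairs against a mean of 5.72, and 1193 shuffles gave as many or more. Thinned to the same 5926254 reads, the wild-type library showed 11570 loci with a read, the rdr2 library 7548 and the rdr6 library 11828. Thinning to equal totals leaves unequal shares of reads outside the top 1% of loci. These were 2.54% in wild type, 0.931% in rdr2 and 2.66% in rdr6, so the lower number in rdr2 may follow from them.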
